A study of Homo sapiens with 6 samples.

How the data were processed

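Gene expression was measured by bulk RNA sequencing in NCI-H1975, a human non-small cell lung cancer cell line. The 6 samples carry 2 treatment labels, a control small interfering RNA (siNC, n = 3) and a small interfering RNA against GFPT2 (siGFPT2, n = 3). Nothing in the labels says whether the 3 replicates of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. Per the labels' protocols, total RNA was extracted with TRIzol, mRNA was enriched on oligo(dT) beads and paired-end libraries were made with a kit for mRNA sequencing. The extraction text also names almonertinib, EGF and EGFR knockdown, which no treatment label of these 6 samples carries. The labels do not say whether the libraries keep strand.

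The values are FPKM (fragments per kilobase of gene length, scaled by the counted fragments of the library), per gene and per library, as deposited by the authors in 1 table of 60960 features. Per the submitters' processing notes, HISAT2, featureCounts and DESeq2 were used by the authors, with no versions; the genome build and the annotation are not given in the sources used here. Of the features, 60605 carry Ensembl gene identifiers and 355 carry provisional names. Symbols were found for 60463 of the Ensembl identifiers in a table of gene names, and 58337 were found in GENCODE release 29 (GRCh38), which gave gene types, GC content and mRNA lengths. The coordinates given for GFPT2 are those of GENCODE 29 on GRCh38 and not of the deposited table. Each column was tied to its sample by its name, and no column of another sample was present.

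Sequencing depth was read from the steps of the FPKM values. All 36981 features above 0 in any library (100.0%) came out as whole reads within a tolerance of 0.0001 reads, with 1 gene length per feature and 1 depth per library. Where the exon length of GENCODE 29 did not give whole reads, the smallest length that did was taken. The 100.0% was therefore partly built in. A length taken in this way can be too short, which would understate the reads of that feature. The recovered depths lay between 21899321 and 27234880 counted fragments per library, and the recovered reads summed to 99.77% to 99.81% of them. GFPT2 rested on 914 to 1058 fragments per library. The recovered reads served to describe depth and in an added alternative with limma-voom.

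The main comparison used limma 3.58.1 in R 4.3.3 on log2(FPKM + 0.1), with lmFit and eBayes with a mean-variance trend, two-sided, group as the only term, and no further scaling between libraries. Features with a mean of at least 1 FPKM over the 6 libraries were kept, which left 12896, of which 261 carry provisional names. A fold change is therefore on the log2(FPKM + 0.1) scale, which understates the change of low genes. P-values were adjusted with the Benjamini-Hochberg method over all features tested, with a threshold of 0.05, and intervals are 95% intervals of the same fit. The GFPT2 level was also tested with an exact two-sided permutation test, whose smallest possible p with 3 against 3 samples is 0.1.

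Before the data were examined, 34 gene lists were written down, covering the hexosamine pathway and glycosylation, nutrient and stress responses, receptor signalling, cell state, cell cycle, innate immune responses, markers of other cell types, and signs of RNA quality. Lists with at least 5 measured members (33) were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists; camera with an estimated correlation and fry were alternatives. Fry asks whether the members of a list move, on balance, one way, and does not compare them with other genes. The test statistics of the lists are not independent, since some genes are in more than 1 list.

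The genes to be named were fixed by rule at the same stage: GFPT2; all measured members of the hexosamine list; the 8 genes rising and the 8 falling with the smallest p among those past the adjusted threshold with at least a 2-fold change, a mean of at least 5 FPKM and groups that do not overlap; up to 4 called members of each list that passes its test or has at least 3 called members; at most the 2 members with the smallest p of every other list; and the 3 most abundant genes. Because no gene was called, the rule left GFPT2, 12 hexosamine genes, the members with the smallest p of each list that did not pass its test and the 3 most abundant genes. The lists that passed had 0 called members, so the rule took none from them. Their 2 members with the smallest p are given all the same: CDK1 and HMMR, IFIT1 and HERC6, and TJP3 and MAL2. Some genes that the rule selects are not reported here. Other genes outside the rule are marked where they appear.

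The model was tested on simulated data. Counts drawn around the real means for the same 12896 features, with a biological coefficient of variation of 0.1 and 200 features changed by a known fold, gave back 42.5% of 1.5-fold changes, 92.0% of 2-fold changes and 99.5% of 4-fold changes. With the same folds added to the real values of 200 features, which keeps the real spread between libraries, 0% of 1.5-fold, 32.0% of 2-fold and 92.0% of 4-fold changes were recovered.

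Alternatives fixed in advance were pseudocounts of 1 and 0.01, no filter, a minimum mean of 5 FPKM, rescaling to a common sum per library (TPM), median centring, quantile normalization, a robust variance estimate, no variance trend, the replicate number as a block, each library left out in turn, and a stricter threshold of 0.01. A further 5 were chosen after seeing the data. They are the fit without both siNC replicate 3 and siGFPT2 replicate 2, removal of a loess trend (span 0.5) on log2 gene length from each library, the length slope of each library as a covariate, and limma-voom on recovered reads with all 6 libraries or without the same pair. Camera with an estimated correlation in each of these fits was also added at that stage. Python 3.11.15 was used for reading the table and for plots.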

Results

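RNA sequencing profiles were analysed from NCI-H1975, a human lung cancer cell line, in 2 groups of 3 libraries that carry the labels siNC (control small interfering RNA) and siGFPT2 (small interfering RNA against GFPT2). GFPT2 encodes an isoform of glutamine-fructose-6-phosphate transaminase, the enzyme of the first and rate-limiting step of the hexosamine pathway, which makes the sugar donor UDP-GlcNAc for glycosylation. The stated purpose was to find genes whose expression differs between the 2 groups. Depth was 22119118, 21899321 and 24493042 counted fragments for siNC replicates 1, 2 and 3, and 22717791, 27234880 and 22198121 for siGFPT2 replicates 1, 2 and 3. Between 12539 and 13109 features reached 1 FPKM in a library. The 3 most abundant transcripts were mitochondrially encoded subunits of cytochrome c oxidase. MT-CO2 stood at 15870 ± 2355 FPKM (SD, n = 3) in siNC and 15470 ± 1730 in siGFPT2, MT-CO1 at 13920 ± 1135 and 14250 ± 624, and MT-CO3 at 13260 ± 1142 and 13420 ± 1107. Mitochondrially encoded genes took 7.90% to 8.77% of the recovered reads of each library.

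The targeted gene was examined first. GFPT2 (ENSG00000131459; chromosome 5, 180300690 to 180353387 on the minus strand in GENCODE 29, GRCh38) was measured over all its exons together, at 9.24 ± 0.925 FPKM in siNC and 8.41 ± 0.734 in siGFPT2 (SD, n = 3 each). The single libraries held 10.13, 9.30 and 8.28 FPKM in siNC and 8.94, 7.58 and 8.72 in siGFPT2, from 1058, 962, 958, 959, 974 and 914 fragments, so the groups overlapped. The log2 fold change was -0.13 ± 0.13 (SE), a change of -8.8% with a 95% interval from -25.9% to 12.3%. It did not pass limma's test (adjusted p = 0.9999; unadjusted p = 0.329) or the exact permutation test (two-sided p = 0.4, where 0.1 is the smallest possible). In this fit the interval excludes a change of GFPT2 mRNA below -25.9% in these libraries. Over the other fits the lower bound ran from -33% without siGFPT2 replicate 1 to -17.8% with the length slope as a covariate. The log2 fold change was -0.065 without siNC replicate 1, -0.21 without siNC replicate 3 and -0.060 without siGFPT2 replicate 2. The level of the target therefore does not separate the 2 labels, and siGFPT2 below means the libraries with that label.

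No other gene of the hexosamine pathway passed the test for a difference between the groups. Of 12 measured members, 0 passed limma's test over all genes, 0 did when adjusted over the list alone and 0 had an unadjusted p under 0.05, with 10 fold changes above 0 and 2 below. GNPNAT1, the glucosamine-6-phosphate acetyltransferase of the pathway, was 5.91 ± 0.726 FPKM in siNC and 7.03 ± 0.801 in siGFPT2, with a log2 fold change of 0.25 (95% interval -0.09 to 0.59). PGM3, the mutase of the following step, was 2.30 ± 0.239 and 2.72 ± 0.314 (log2 0.23, -0.12 to 0.58), and UAP1, which makes UDP-GlcNAc, was 14.8 ± 0.839 and 16.2 ± 0.766 (0.14, -0.10 to 0.38). GFPT1, the paralog of GFPT2 that catalyses the same step, was 7.41 ± 1.21 and 7.97 ± 1.21 FPKM (0.11, -0.31 to 0.52). OGT and OGA, the enzymes that add and remove O-GlcNAc on proteins, had wider intervals, of -0.71 to 0.93 around 0.11 and of -0.40 to 0.64 around 0.12. The remaining log2 fold changes were 0.12 for GNPDA2, 0.10 for GNPDA1, 0.07 for RENBP, 0.00 for UAP1L1, -0.05 for NAGK and -0.10 for AMDHD2. As a list, the hexosamine genes had a median log2 fold change of 0.11, and camera gave an adjusted p of 0.218 (adjusted p = 0.594 with an estimated correlation).

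**Figure D1:**
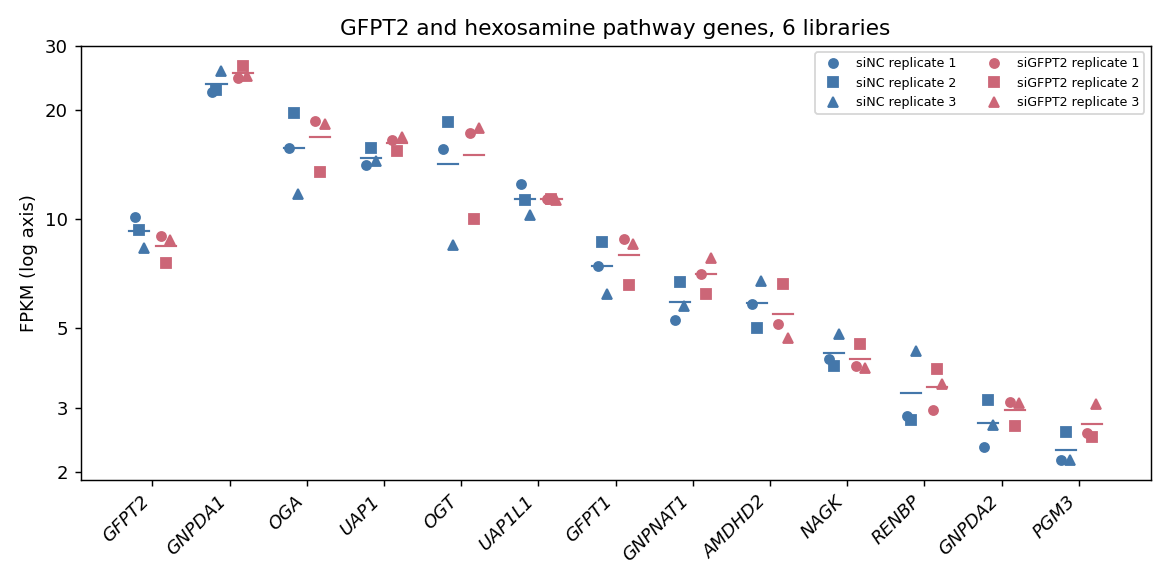
FPKM (log axis) of GFPT2 and the 12 measured hexosamine pathway genes in each library; points are libraries, with a shape per replicate number and a colour per group, and short lines are group means (n = 3). The GFPT2 points of siNC lie between 8.28 and 10.13 FPKM and those of siGFPT2 between 7.58 and 8.94, so the groups overlap.

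Across the transcriptome, no gene passed the test for a difference between the groups. Of 12896 features tested with limma, 0 passed an adjusted p of 0.05, in either direction, and the smallest adjusted p was 0.9999. At an unadjusted p under 0.05 there were 84, with 42 higher and 42 lower in siGFPT2. By chance 645 would be expected if no structure were shared between libraries of both groups. The division by direction was 31 higher and 59 lower with median centring and 32 and 59 with quantile normalization. The limma-voom fit on recovered reads called 0 as well, with 59 at an unadjusted p under 0.05. The middle of the distribution was close to 0, with a median log2 fold change of 0.03 and 5th and 95th percentiles of -0.16 and 0.24. For 11962 features (92.8%) the 95% interval excluded a 2-fold change in either direction. The groups did not overlap for 3.53% of features, against 10% expected by chance for 3 against 3 under the same condition. The deviation shared by siNC replicate 3 and siGFPT2 replicate 2, described below, breaks this condition. Neither value therefore shows fewer differences than chance. In the simulation that added known folds to the real values, 0% of 1.5-fold, 32.0% of 2-fold and 92.0% of 4-fold changes were recovered, so changes under 2-fold were mostly not detectable with this spread. Without both siNC replicate 3 and siGFPT2 replicate 2, which stand apart from the other libraries, limma called 0 genes and had 751 at an unadjusted p under 0.05 (514 higher, 237 lower), and limma-voom called 3 (NBPF14, MALAT1 and NSFP1, named after their values were seen). With 1 library left out limma called 0, and the unadjusted count was 161 without siNC replicate 2 (121 higher, 40 lower), 520 without siNC replicate 3 (421 higher, 99 lower), 54 without siGFPT2 replicate 1 (30 higher, 24 lower) and 50 without siGFPT2 replicate 3 (23 higher, 27 lower). With the length slope as a covariate it was 704 (480 higher, 224 lower), with 0 called.

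The 34 gene lists held 738 measured genes, of which 0 passed the test over all genes or when adjusted over the list alone, and 2 had an unadjusted p under 0.05. List medians lay between -0.04 and 0.11 on the log2 scale. Centring the libraries on their median gene moved all fold changes by -0.05, and 21 of the 34 list medians changed sign or went to 0 with it or with another of the 3 scalings tried. The 13 that did not were those of G2 and mitosis, interferon, epithelial markers, apoptosis, collagens and laminins, DNA replication, hexosamine, alveolar markers, glycolysis, mucin-type glycosylation, chaperones, EGFR family and sialic acid. For 8 of the 33 tested lists camera's direction and the median had opposite signs, and camera's direction and the mean also had opposite signs for 8. Camera compares a list with all other genes, whose median was 0.03.

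At the preset correlation 3 lists passed camera, and 0 did with an estimated correlation or with fry. In some fits the option with an estimated correlation also ended calls of lists whose estimate lay under the preset 0.01. A loss with that option therefore does not decide against a list whose estimate lay under the preset. In the main fit the estimates of the 3 passing lists lay above it. They were 0.0668 for G2 and mitosis, 0.0297 for interferon and 0.0116 for the epithelial markers. An exact permutation test of list scores gave p = 0.2 for G2 and mitosis, 0.2 for interferon and 0.5 for the epithelial markers. Its smallest possible value is 0.1. The median deviations of single libraries overlapped between the groups for each list. siNC replicate 2 stood at 0.027, 0.042 and -0.045, and siGFPT2 replicate 2 at -0.011, -0.01 and -0.005. The remaining libraries did not overlap. The counts of members given next do not measure spread between libraries. The genes of G2 phase and mitosis had a median of 0.09, with 28 of 36 members above 0 (camera adjusted p = 0.0159; adjusted p = 0.594 with an estimated correlation). CDK1, the kinase that drives entry into mitosis, was 18.1 ± 2.10 FPKM in siNC and 21.1 ± 0.903 in siGFPT2, a log2 fold change of 0.23 (-0.06 to 0.51), and HMMR, a spindle protein and hyaluronan receptor, was 12.9 ± 3.22 and 15.6 ± 1.05 (0.30, -0.14 to 0.75). The type I interferon response had a median of 0.10, with 30 of 34 members above 0 (camera adjusted p = 0.0159; adjusted p = 0.483 with an estimated correlation). Its antiviral gene IFIT1 was 10.1 ± 1.69 and 11.8 ± 0.178 FPKM (0.24, -0.09 to 0.58), and HERC6 was 4.92 ± 0.252 and 5.55 ± 0.328 (0.17, -0.09 to 0.43). The epithelial markers had a median of -0.03, with 18 of 26 members below 0 (camera adjusted p = 0.0314; adjusted p = 0.483 with an estimated correlation). TJP3, a tight junction scaffold, was 4.60 ± 0.176 and 3.95 ± 0.166 FPKM (-0.22, -0.47 to 0.04), while MAL2, an apical transport protein, was 30.4 ± 6.74 and 35.9 ± 3.15 (0.26, -0.17 to 0.69). Over 21 other fits, camera's adjusted p at the preset correlation ranged from 0.000222 to 0.132 for G2 and mitosis (16 passing), from 0.00355 to 0.106 for interferon (15 passing) and from 0.0196 to 0.354 for the epithelial markers (9 passing), and 0 lists passed without siGFPT2 replicate 3 or with no filter on low values. With 1 library left out, the mitosis call ended in 4 of 6 fits (all but those without siNC replicate 2 or siGFPT2 replicate 1), the interferon call in 5 (all but that without siGFPT2 replicate 1) and the epithelial call in 5 (all but that without siNC replicate 2), with adjusted p up to 0.132, 0.105 and 0.210. Without both siNC replicate 3 and siGFPT2 replicate 2, 5 lists passed: G2 and mitosis and the interferon response (both 0.00939), but not the epithelial markers (0.103), and, with RNA quality lists among them, cytosolic ribosomal proteins (1.83e-08, up), the respiratory chain (0.000889, up) and collagens and laminins (0.000342, down). None of these 5 passed with an estimated correlation in the same fit (adjusted p = 0.667 for each). The direction of the ribosomal and respiratory chain lists turned with the library left out: camera called both up without siNC replicate 3 (2.10e-15 and 3.47e-08), and both down without siNC replicate 1 (2.33e-05 and 0.0182), siNC replicate 2 (1.83e-05 and 0.00734) or siGFPT2 replicate 2 (7.55e-07 and 0.00142). With an estimated correlation, which was 0.964 for the ribosomal and 0.825 for the respiratory chain list with all libraries, the adjusted p of these calls was between 0.716 and 0.887 in the same fits.

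Glycosylation and nutrient lists, which lie downstream of or around the hexosamine pathway, held 0 called genes, and 0 of them passed camera. N-glycan assembly had a median of 0.05 over 29 genes, mucin-type O-glycosylation 0.05 over 14, sialic acid synthesis 0.08 over 13, and hyaluronan and glycosaminoglycan synthesis 0.02 over 23. C1GALT1, which extends the core of mucin-type glycans, was 3.64 ± 0.518 FPKM in siNC and 4.25 ± 0.556 in siGFPT2 (0.22, -0.16 to 0.60), GALNT12 had a log2 fold change of 0.16, and the sialic acid enzymes CMAS and NANP had 0.19 and 0.18. UGP2, which makes UDP-glucose, was 7.73 ± 1.65 and 9.37 ± 0.150 (0.30, -0.11 to 0.71), and the glycosaminoglycan enzyme EXTL2 had 0.24. In the N-glycan list the glucosidase MOGS had -0.10. Glutamine metabolism had a median of 0.05 over 15 genes, with 0.14 for GMPS. Glycolysis had a median of -0.004 over 23 genes, with 0.12 for the glucose transporter SLC2A3. The aldolase gene ALDOA had -0.16, at 9.03 ± 0.507 and 8.13 ± 1.08 FPKM, and is uncertain, since another protein-coding gene and an antisense gene of GENCODE 29 overlap it. The ATF4 amino acid response had a median of 0.00 over 34 genes. Its member CBS, which makes cystathionine from homocysteine and serine, was 3.40 ± 0.718 FPKM in siNC and 2.30 ± 0.414 in siGFPT2. Its log2 fold change was -0.54 (-1.03 to -0.04), with an unadjusted p of 0.0369 and an adjusted p of 0.9999 by limma. The groups overlapped, with 2.63 FPKM in siNC replicate 1 and 2.73 in siGFPT2 replicate 1. PSAT1, of serine synthesis, had 0.21. Endoplasmic reticulum chaperones had a median of 0.07 over 22 genes, with 0.31 (-0.07 to 0.69) for the co-chaperone DNAJB9 and 0.16 for DNAJB11. The sterol and lipid lists had medians of 0.02 over 23 and 0.02 over 17 genes, with 0.28 for HMGCS1, of the mevalonate pathway, 0.21 for SC5D, 0.15 for ELOVL6 and 0.16 for ELOVL5. The NRF2 list had a median of 0.05 over 22 genes, with -0.11 for TKT, of the pentose phosphate pathway, and the hypoxia list had -0.0001 over 23 genes, with 0.18 for ERO1A and 0.16 for P4HA1.

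Lists of signalling and cell state also held 0 called genes, and apart from the epithelial markers 0 of them passed camera with all 6 libraries as deposited. Collagens and laminins passed, downward, in 5 of 21 other fits, among them the fit with the length trend removed (adjusted p = 0.0117) and the fits without siNC replicate 3 (3.14e-05) or siGFPT2 replicate 1 (0.00296), and YAP and TAZ targets passed downward without siNC replicate 3 (0.0362), against camera's upward direction with all libraries. With an estimated correlation in the same fits, the adjusted p was 0.948, 0.716 and 0.834 for collagens and laminins and 0.716 for YAP and TAZ targets. EGFR family receptors and ligands had a median of 0.06 over 13 genes, with 0.29 (-0.17 to 0.76) for the ligand BTC and 0.15 for HBEGF. EGFR itself, named here after its values were seen, was 22.8 ± 10.2 FPKM in siNC and 22.5 ± 7.30 in siGFPT2 (log2 0.04, -0.98 to 1.06). ERK pathway output had a median of 0.04 over 20 genes, with 0.17 for FOS and 0.12 for IER3. The mesenchymal markers had a median of -0.0007 over 16 genes, with -0.07 for SNAI1 and 0.13 for CALD1, and the matrix collagens and laminins -0.04 over 18, with -0.11 for COL6A2 and -0.12 for COL18A1. TGF-beta response genes had a median of 0.01 over 22, with -0.17 for the ligand TGFB1 and -0.14 for LTBP3, and YAP and TAZ targets 0.04 over 20, with 0.27 for ANKRD1 and 0.14 for NT5E. The alveolar lineage markers had a median of -0.03 over 8 genes, with -0.18 for AGER and -0.12 for the transcription factor FOXA2.

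Lists of proliferation, survival and immunity other than mitosis and interferon gave the same count of 0 called genes, and 0 of them passed camera in the main comparison. Apoptosis regulators passed, upward, with a minimum mean of 5 FPKM (adjusted p = 0.0481), and DNA replication with quantile normalization (0.0454) and with the length slope as a covariate (0.0421). With an estimated correlation in the same fits, the adjusted p was 0.499, 0.682 and 0.814. DNA replication genes had a median of 0.08 over 38 genes (camera adjusted p = 0.137), with 0.17 for GINS3 and 0.20 for GINS1. Apoptosis regulators had a median of 0.08 over 27 genes (camera adjusted p = 0.135), with 0.21 (-0.03 to 0.45) for PMAIP1 and 0.26 for CASP10. The p53 targets had a median of 0.02 over 18 genes, with 0.25 for CCNG1 and 0.25 for the death receptor FAS. Inflammatory cytokine genes had a median of 0.01 over 24 genes, with 0.29 (-0.06 to 0.64) for CXCL1 and 0.34 (-0.16 to 0.83) for CXCL8. MHC class I and checkpoint ligand genes had 0.02 over 20, with -0.14 for NECTIN2 and 0.15 for CD47. The small RNA silencing machinery had 0.04 over 11 genes, with 0.23 for PRKRA and 0.12 for XPO5.

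**Figure D2:**
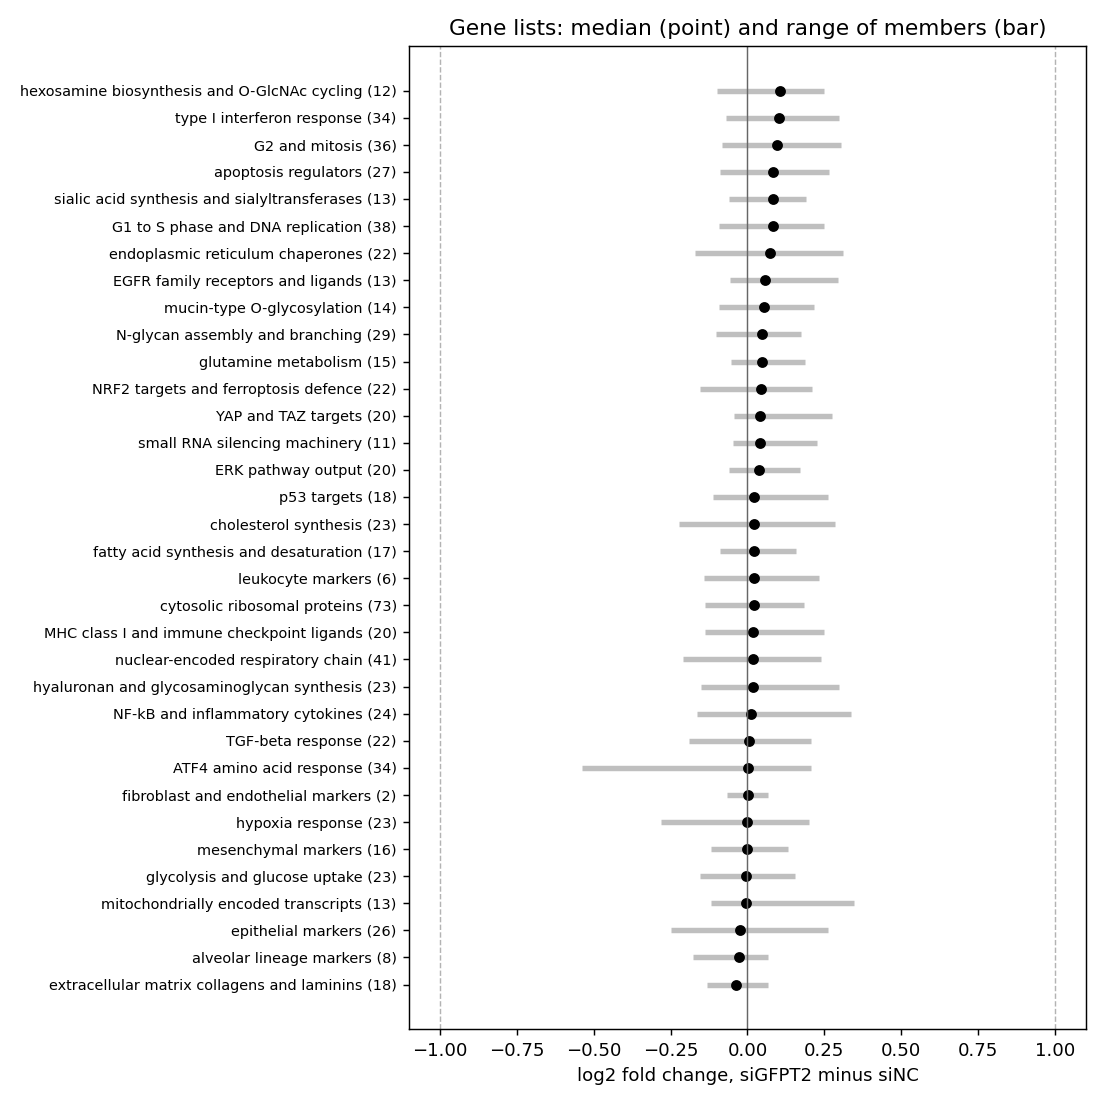
Log2 fold change (siGFPT2 minus siNC) of the 34 gene lists, with the number of measured genes in brackets; points are medians, bars run from the lowest to the highest member, and dashed lines mark a 2-fold change. The medians lie between -0.04 and 0.11, and no member reaches a 2-fold change.

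Markers of other cell types were few. Of the leukocyte markers 6 reached the minimum level, with a median of 0.02, and LCP1, an actin-bundling protein that is also made by many cancer cell lines, had an unadjusted p of 0.0496 at 6.17 ± 0.220 FPKM in siNC and 7.27 ± 0.0418 in siGFPT2 (log2 0.23, 0.0005 to 0.47; limma adjusted p = 0.9999). CD14 had -0.14. Of the fibroblast and endothelial markers 2 reached it, ENG at -0.07 and COL1A1 at 0.07, and this list was too small for the set test. The lists that bear on RNA quality held 0 called genes and did not pass camera with all 6 libraries. Cytosolic ribosomal proteins had a median of 0.02 over 73 genes, with 0.18 (-0.57 to 0.93) for RPS25 and 0.16 for RPL6, which are uncertain, since reads can be shared with processed pseudogenes. The respiratory chain genes of the nucleus had 0.02 over 41, with 0.13 for NDUFS1 and 0.12 for SDHC, and the mitochondrially encoded transcripts -0.01 over 13, with 0.35 for MT-ATP8 and -0.12 for MT-ND6.

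The largest differences between libraries did not follow the groups. The first principal component held 68.0% of the variance of the tested features, with loadings of 0.71 for siNC replicate 3 and 0.41 for siGFPT2 replicate 2 and between -0.36 and -0.25 for the other 4 libraries. The deviations of siNC replicate 3 and siGFPT2 replicate 2 from the gene means correlated with r = 0.709 across genes, which are not independent replicates. Among 10678 protein-coding genes, the deviation was lower for longer mRNAs in these 2 libraries, with Spearman's rho of -0.716 and -0.715 across genes, and higher for them in siNC replicates 1 and 2 (0.368 and 0.692) and siGFPT2 replicates 1 and 3 (0.640 and 0.566). For mRNAs under 1 kb the median deviation was 0.43 in siNC replicate 3 and 0.27 in siGFPT2 replicate 2, and for mRNAs over 8 kb it was -0.54 and -0.36. The ribosomal protein list stood at 0.54 and 0.34 in these libraries and between -0.30 and -0.12 in the others. EGFR, a long mRNA named after its values were seen, held 11.2 FPKM in siNC replicate 3 and 14.0 in siGFPT2 replicate 2, against 26.7 and 30.4 in the other siNC libraries and 27.1 and 26.2 in the other siGFPT2 libraries. No pair of libraries agreed within counting error, so none was taken for 1 library deposited again. The closest, siGFPT2 replicates 1 and 3, had a mean chi-square per gene of 2.90, where counting error alone gives a value near 1; this does not bear on whether the libraries came from separate cultures.

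**Figure D3:**
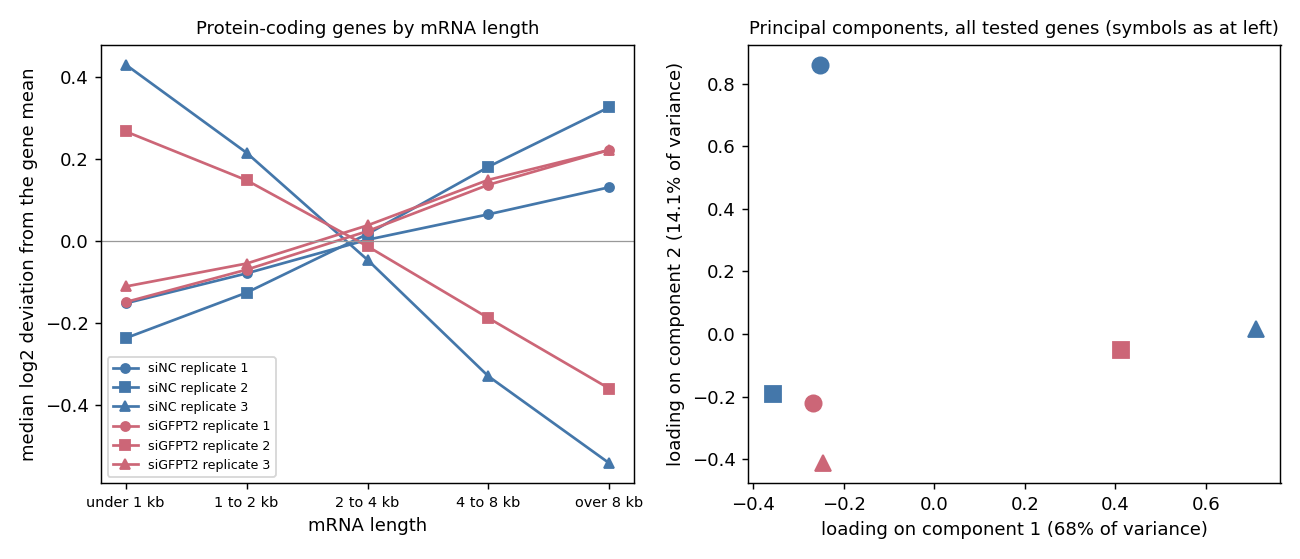
Left, median log2 deviation from the gene mean in 5 classes of mRNA length for each library (protein-coding genes); right, loadings of the 6 libraries on the first 2 principal components of all tested features, with 68.0% and 14.1% of the variance. Colours are groups and shapes are replicate numbers; siNC replicate 3 and siGFPT2 replicate 2 slope down with length, from 0.43 and 0.27 to -0.54 and -0.36, and lie apart from the other 4 libraries on the first component.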

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

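The added fits (without both siNC replicate 3 and siGFPT2 replicate 2, length trend removed, length slope as a covariate, and limma-voom on recovered reads) and the estimated correlation in each fit were chosen after seeing the data. The count of genes past the threshold stayed 0 under all alternatives run but 1: limma-voom on recovered reads without both siNC replicate 3 and siGFPT2 replicate 2 called 3, NBPF14, MALAT1 and NSFP1; the cause was not tested. At the stricter threshold of 0.01, 0 genes passed in the main comparison, and neither these 3 calls (adjusted p = 0.0308 each) nor the 3 list calls (0.0159, 0.0159 and 0.0314) would pass. GFPT2 stayed below 0 and short of the threshold under every alternative run, between -0.060 without siGFPT2 replicate 2 and -0.21 without siNC replicate 3, so single libraries move its fold change by over 1.5 times. The number of lists past camera was 3 in the main comparison, 0 with an estimated correlation, 0 with fry, 0 with no filter on low values, between 0 and 4 with 1 library left out (0 without siGFPT2 replicate 3), and 5 without both libraries, by limma or by limma-voom on recovered reads; the cause was not tested. Besides the 3, camera called 6 lists in at least 1 of 21 fits: ribosomal proteins in 7 and the respiratory chain in 6, both upward or downward with the library left out, collagens and laminins in 5, DNA replication in 2, and apoptosis regulators and YAP and TAZ targets in 1 each, the last against the direction with all libraries. All these calls are at the preset correlation: over the 22 fits 65 calls of lists were made with it, and 0 of them held with an estimated correlation in the same fit (smallest adjusted p = 0.470). The size of the correlation alone does not account for every loss. The interferon list in limma-voom with all 6 libraries had an estimate of 0.000766, under the preset 0.01. Its camera adjusted p still went from 0.0173 to 0.555. Such a loss therefore does not decide against a list whose estimate lay under the preset. In the main fit the estimate lay above it for G2 and mitosis (0.0668), ribosomal proteins (0.964) and the respiratory chain (0.825). For lists like these the preset may understate the correlation, and their calls at the preset are less certain. Same-numbered deviations from the group means correlated at 0.473, -0.719 and -0.570 for replicates 1, 2 and 3, and siNC replicate 3 went with siGFPT2 replicate 2 (0.792). These 2 deviating libraries carry different numbers, which largely sets the negative values. The correlations therefore cannot decide whether the replicate numbers pair the libraries. With the replicate block 0 genes and 2 lists passed, and GFPT2 stayed at -0.13. The 81 other genes that the rule selected or that were taken from the 3 passing lists had 1678 values under 21 alternatives. Of these values, 40 changed sign or went to 0, in 17 genes, all with p-values short of the threshold before and after. UAP1L1 went from 0.0042 to -0.0487 with median centring, -0.0229 with quantile normalization, -0.0367 with the length trend removed, -0.0291 with limma-voom, -0.0929 with limma-voom without both libraries and -0.0662 without both. MT-CO1 went to -0.0172 with median centring, 0 with quantile normalization and -0.0189 with limma-voom without both, MT-CO2 to 0 with quantile normalization, and MT-CO3 to -0.0354, 0 and -0.0156 there, -0.010 with the length trend removed and -0.0166 with limma-voom; the cause was not tested. With 1 library left out, the log2 fold changes that changed sign ranged as follows: RENBP -0.0339 to 0.27, RPS25 -0.0823 to 0.52, RPL6 -0.0572 to 0.46, MT-CO3 -0.0495 to 0.0778, NAGK -0.12 to 0.0327, GFPT1 -0.0144 to 0.24, OGT -0.22 to 0.38, UAP1L1 -0.0649 to 0.0755, OGA -0.0744 to 0.29, AMDHD2 -0.24 to 0.0055, ELOVL5 -0.0209 to 0.30, COL1A1 -0.0777 to 0.16, CD14 -0.26 to 0.0609, CALD1 -0.0538 to 0.33, MT-ND6 -0.30 to 0.0073, MT-CO2 -0.12 to 0.0861 and MT-CO1 -0.0294 to 0.0877. The edgeR and DESeq2 fits foreseen for whole reads were not run, and limma-voom was the only model fitted to the recovered reads. Depth was not the limit for GFPT2, at 914 to 1058 fragments per library; across genes the spread between libraries limited what could be called, since added 2-fold changes were recovered for 32.0% of genes, against 92.0% in counts drawn with a biological coefficient of variation of 0.1.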

Other observations

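The tests of label exchanges, of mRNA length, of the share of protein-coding genes and of other splits for the gene count were chosen after the result was seen, as were the fits without siNC replicate 3 and siGFPT2 replicate 2 and the genes named next.

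The values of a few further RNAs are given here, none past limma's adjusted threshold with all 6 libraries; non-coding RNAs were not tested as a group. MALAT1, a nuclear long non-coding RNA, held 13.6, 14.3 and 11.8 FPKM in siNC and 22.6, 16.4 and 23.2 in siGFPT2, higher in 3 of 3 libraries, with a log2 fold change of 0.63 (95% interval 0.24 to 1.02; limma adjusted p = 0.9999). In limma-voom on recovered reads without siNC replicate 3 and siGFPT2 replicate 2 it was 0.69 (adjusted p = 0.0308), by limma without them 0.71 (adjusted p = 0.232), and by limma with the length trend removed 0.58 (adjusted p = 0.9998). NEAT1, another nuclear long non-coding RNA, was 0.21 (-0.23 to 0.65) and the long non-coding MIR210HG was 0.05 (-0.48 to 0.58); the groups overlapped for both. RN7SL1, the RNA of the signal recognition particle, was 0.72 (-0.04 to 1.49), also with overlapping groups. The spliceosomal RNVU1-1 was 1.40 (0.63 to 2.17), at 0.906 FPKM in siNC and 2.38 in siGFPT2. The nucleolar SNORD15B was 1.38 (0.62 to 2.13), at 0.591 and 1.60. Both are short, with lengths of 164 and 146 bases, so these low levels rest on few fragments. The libraries were also enriched for mRNA, so neither value is a reliable measure of these RNAs. The pseudogene LSM12P1 was 0.78 (0.48 to 1.09), with 14.2, 14.3 and 14.2 FPKM in siNC and 26.1, 20.9 and 27.1 in siGFPT2. NBPF14 was 0.74 (0.37 to 1.11). It belongs to a family of near-identical copies, so its reads are uncertain, as are those of pseudogenes. The pseudogene NSFP1 was 2.62 with all 6 libraries (limma adjusted p = 0.9999). In limma-voom without siNC replicate 3 and siGFPT2 replicate 2 it was 4.89 (adjusted p = 0.0308), so its value moved with the fit and the libraries used.

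siNC replicate 3 and siGFPT2 replicate 2 deviated together, with more signal in short mRNAs and less in long ones. Their deviations stayed correlated after removal of trends on annotated length. After removal of the trend on gene length the correlation was 0.641 (0.598 to 0.678), from 0.709. After removal of the trend on mRNA length in protein-coding genes it was 0.790 (0.743 to 0.818), from 0.893, with 56.6% of the variance of the deviations left. Annotated lengths may differ from those of the transcripts made in these cells, so this cannot decide whether length was the whole cause. A trend on GC content left 0.703 (0.665 to 0.743), from 0.712, in the 97.4% of features with a value. The ranges in brackets after these correlations are not intervals of the limma fit. They concern these 2 libraries only and do not measure variation between libraries. These values do not test an exchange of these 2 labels. An exchange would have the pair deviate in opposite directions (0.709 was found). It would also have siNC replicate 3 go with siGFPT2 replicates 1 and 3 (-0.707 and -0.619). The pair was picked because it deviates together and apart from the other libraries, which largely set these signs in advance. siNC replicate 3 also went against siNC replicates 1 and 2 (-0.543 and -0.723), so these values do not say which label it should carry. A shared difference in RNA integrity, library preparation or culture may add to the length trend and stays open, since the labels give no batch and both groups hold 1 such library; no biological explanation was tested.

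The GFPT2 level differed little between the labels. No exchange of 1 siNC label with 1 siGFPT2 label gave a strong difference. The largest absolute log2 difference over the 9 exchanges was 0.205, against 0.133 as labelled. All libraries lay between 7.58 and 10.13 FPKM, so no regrouping could have shown a strong reduction. These values therefore cannot decide whether labels were exchanged. After removal of the fitted gene length trend the log2 fold change was -0.17 (-0.43 to 0.09), so that trend did not hide a much larger reduction. Its removal left 82.7% of the variance of the deviations, so this says nothing on the rest of the shared deviation. A candidate explanation that stays open is that the libraries were made at a time, dose or from cultures in which the mRNA was hardly reduced, or that samples from outside the series were mixed in; the labels give no time, dose or protein level to test this.

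The genes with the smallest p-values were rarely protein-coding: 24 of the 84 features at an unadjusted p under 0.05 (28.6%), against 82.8% of the features tested (Fisher's exact test, two-sided, p = 5.51e-28, across genes, which are not independent). Of the 84, 15 had no gene type and count as not protein-coding. Without siNC replicate 3 and siGFPT2 replicate 2 the share was 63.0% by limma; by limma-voom on recovered reads it was 50.8% with all 6 libraries and 80.9% without them, so the method moves it too. With 1 library left out it was 13.8%, 48.4% and 59.4% without siNC replicates 1, 2 and 3, and 13%, 22.9% and 16% without siGFPT2 replicates 1, 2 and 3. The spread that siNC replicate 3 and siGFPT2 replicate 2 add to protein-coding genes may account for some of it. This cannot be told apart from a difference in non-coding RNA between the labels, because the limma value of 63.0% lies between the bounds set for the test. The limma-voom value of 80.9% lies close to the 82.8% of features tested. Among the 84 were 13 processed pseudogenes and 9 microRNA genes. Whether features with few fragments make up part of the 84 was not tested, so no difference in non-coding RNA is shown.

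All 10 splits of the 6 libraries into 3 against 3 called 0 genes, so the real value was 0 and the highest other 0, and 10 splits are too few for a share under 0.05. At an unadjusted p under 0.05 the real split had 84 genes and the others between 45 and 4146. The split with 4146, siNC replicates 1 and 3 with siGFPT2 replicate 2 against the rest, puts the 2 deviating libraries on 1 side, which points to a structure of the samples. The other splits that do so had 433, 1969 and 2786. The splits that part these 2 libraries had 84 (the real one), 66, 62, 49, 49 and 45. Among these the real split was the highest, but they are too few for a test. For the gene lists, 6 of the 10 splits, the real one included, had at least the 3 lists that passed camera, and the highest other had 10; 10 splits are again too few for a share under 0.05.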
